A study of Mus musculus with 6 samples.

How the data were processed

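Lens RNA from mouse pups on postnatal day 1 was measured by RNA sequencing in 3 libraries labelled Gclc KO and 3 labelled Gclc CON. Per the labels' protocols, lenses were frozen in RNAlater, RNA was extracted with a column kit for small samples (RNeasy Micro), and libraries were made from total RNA with a low-input NEBNext kit. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with HISAT2 2.1.0 to mm9, counted per gene with featureCounts 1.6.4 and processed with DESeq2 (version given as 2.11.0.6). The deposited table holds 27179 Entrez gene identifiers by 6 libraries, in log2 units after the variance-stabilising transformation that the authors made with DESeq2; its lowest value, 6.504, is that of a gene without reads. The labels name no Cre driver, deleted exons, sex, litter or batch, and the number of animals per library is not stated. The library name of CON 2 carries another lane suffix than those of the other libraries. The labels do not say whether CON 2 was run apart.

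The transformation was inverted per library to read counts. Every value came within 0.1 of a whole number (100.0% of values, largest distance 0.017), and the recovered size factors equalled those of the median-of-ratios method, computed anew from the recovered reads. The size factors were 0.9302, 0.312 and 0.6658 for CON 1 to 3 and 1.7051, 1.6335 and 1.8579 for KO 1 to 3. Normalised reads are the recovered reads divided by these factors. Reads carry no molecular identifiers, so a count of reads is not a count of molecules. Libraries had from 13590 (CON 2) to 17093 (KO 3) genes with reads. CON 2 was the shallowest library, with 20361430 reads in genes, of which crystallins took 68.37%, against 61219009 and 46.65% in KO 3. For a gene without reads in CON, a lower bound on the ratio was formed with 3 reads over the CON libraries together. Among genes with 1 to 100 reads, 51.5% (KO 2) to 55.1% (CON 2) had an even count, and every library had more genes with 2 reads than with 1 (411 against 247 in CON 2). Both mates of some read pairs may thus have been counted, and the bound was also formed with 6 reads. Identifiers were matched to symbols with the mouse reference annotation (GRCm38), used for names, transcript length and the order of neighbouring genes only. It matched 25275 identifiers. The other 1904 held at most 0.276% of the reads of a library, and they stayed in the tests without a symbol. 7954 genes had no reads in any library.

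KO was compared with CON with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on the deposited log2 values, without a covariate. Genes with a mean at least 1 unit above the lowest value of the table were tested (11468), and calls were made at a Benjamini-Hochberg adjusted p under 0.05. The shared prior variance had 7.60 degrees of freedom. 35 gene lists with 861 symbols, of which 5 were not matched, were written from general knowledge. The 32 lists with 4 or more tested members, the sex-linked genes aside, were tested with camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. Members were counted at an adjusted p under 0.05 over all genes and again adjusted over the list alone. The groups, the test, the filter, the lists, the rule for naming genes and the first alternatives were chosen before the data were examined. The rule named Gclc, Gclm, Pax6, the 12 called genes with the largest differences in each direction whose KO values all lay on one side of the CON values, and for each list up to 2 members with the smallest p in each direction. Genes of unnamed or predicted loci and sex-linked genes were left out, and some genes that the lists hold are not reported here by name. Further members of lists were named because 5 or fewer were called, and these were chosen after their values were seen.

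The alternatives were no filter, a filter of 3 units, equal library medians, quantile normalisation, voom on recovered reads with the size factors, log2 of normalised reads plus 1, eBayes without trend, library weights, the replicate number as a block, a covariate for the style of library name (shared by KO 2 and KO 3), a threshold of 1 on the log2 difference, each library left out in turn, camera with an estimated correlation, and fry. Added after the data were seen were voom with total reads or non-crystallin reads as library size, a fit without crystallins, and the removal of a trend with transcript length by loess. Equal replicate numbers were checked for pairing by the correlation of residuals between KO and CON libraries. The correlations of equal numbers were -0.364, -0.128 and -0.14, so the numbers were not used as pairs in the reported fit. In a test on simulated data of 3 libraries per group, with 100 genes changed by each of 2 sizes, the fit recovered 22% of genes changed by 1 log2 unit and 75% of those changed by 2, with 2 false among 99 calls. In a simulation with genes drawn independently and 1 of the 32 lists shifted by 1 unit, camera called that list and 0 others. Without correlation between genes, it cannot show how often lists are called falsely in these data. There the estimated correlation was 0.87 for crystallins. The inversion recovered 100.0% of simulated counts of 20000 genes.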

Results

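RNA was sequenced from lenses of mouse pups of a mixed B6/FVB background on postnatal day 1. 3 libraries came from lenses labelled Gclc KO and 3 from controls labelled Gclc CON (KO 1 to 3 and CON 1 to 3 here). Gclc encodes the catalytic subunit of glutamate-cysteine ligase, the rate-limiting enzyme of glutathione synthesis, and the series title names glutathione synthesis, eye development and the eye transcription factor PAX6 as its subject. The comparison asked which transcripts differ between KO and CON lenses at this age. CON 1 to 3 held 43384443, 20361430 and 42313567 reads in genes, and KO 1 to 3 59964578, 45842484 and 61219009. The 16 crystallin genes, which encode the main soluble proteins of the lens, took 64.7% ± 4.60 (SD, n = 3) of the reads in CON and 44.9% ± 3.82 (SD, n = 3) in KO. Normalised read counts below are reads divided by the size factors of the deposited values, given as mean ± SD with n = 3 per group. Log2 differences are KO minus CON on the deposited variance-stabilised scale, which shrinks differences of genes with few reads. The labels do not say that the libraries came from separate animals, so the p-values measure only the spread between these 6 libraries, and the floor given for a gene without reads covers counting error only.

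**Figure D1:**
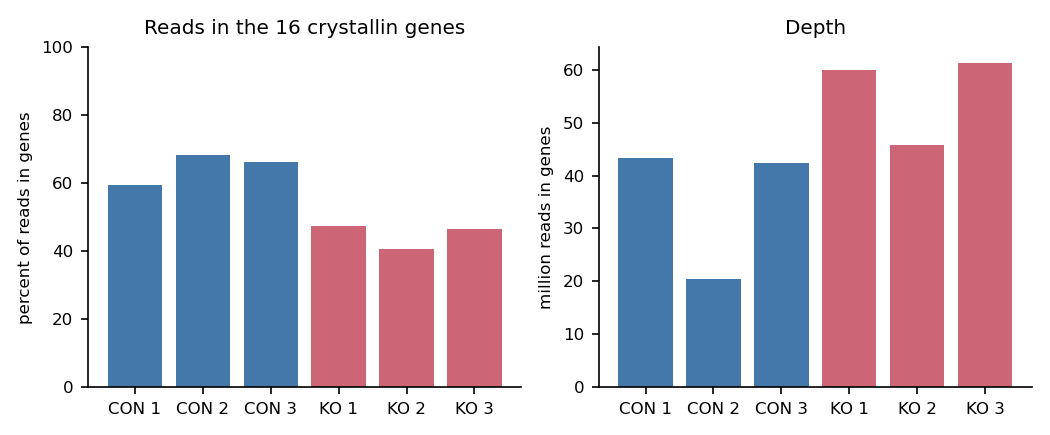
Reads assigned to genes in each of the 6 libraries. The left bars give the percent of reads in the 16 crystallin genes and the right bars the reads in genes. The crystallin share lay between 40.52% and 47.53% in KO and between 59.51% and 68.37% in CON, and the KO libraries were the deeper ones.

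Gclc (Entrez 14629) was lower in all 3 KO libraries than in any CON library, with 18.2, 73.5 and 59.2 normalised reads in KO 1 to 3 against 182, 288 and 175.7 in CON 1 to 3 (50.3 ± 28.7 against 215 ± 63.4; log2 difference -1.01, SE 0.28, adjusted p = 0.0387). Lens fibre genes and crystallins were lower in part in KO lenses, among them the lens water channel gene Mip (202930 ± 21338 normalised reads in CON and 58794 ± 7828 in KO). Macrophage markers, chemokines, p53 targets, immediate early genes and feedback targets of FGF and ERK signalling were higher in part, among them the cell cycle inhibitor gene Cdkn1a (67.8-fold; 107 ± 59.3 in CON and 7257 ± 786 in KO). The lists of these genes passed with a preset correlation between genes, and none passed with an estimated one (adjusted p = 0.189 for macrophage markers and 0.412 for crystallins). Pax6 itself rose 1.89-fold (5970.4 ± 1314 in CON and 11288 ± 822 in KO; adjusted p = 0.0156), together with the retinal gene Six6.

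Of 11468 genes tested with limma, 793 were higher and 504 lower in KO at an adjusted p under 0.05, and 654 and 335 of these differed by 1 log2 unit or more. Of 32 gene lists, 12 were higher and 6 lower by camera with a preset correlation between genes, and 0 passed with a correlation estimated from these 6 libraries. With reads divided by the library total, calls were lost for the lists of cell cycle (adjusted p = 0.133), interferon (0.610), epithelial-mesenchymal transition (0.357), photoreceptor (0.357), inner retina (0.0984), pigment cell (0.0793), respiratory chain (0.498) and mitochondrially encoded genes (0.141). The share of higher genes depended on the scaling. It was 61.1% with the values as deposited, 47.3% with equal library medians (643 higher and 717 lower), 47.1% with voom on recovered reads (421 and 472) and 97.5% with reads divided by the library total (3314 and 85), where the median over all tested genes stood at 0.86. The counts changed when single libraries were left out, upward or downward. Each of these fits had 1 library fewer and thus fewer degrees of freedom. Without CON 1 the counts were 1085 higher and 858 lower, without CON 2 524 and 277, and without CON 3 687 and 445. Without KO 1 they were 502 and 321, without KO 2 533 in all (357 higher), and without KO 3 478 and 241. The Gclc call was lost without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.130) and with voom on recovered reads (adjusted p = 0.0609), and the sources used here do not say which part of the gene was altered. Gclm, which encodes the modifier subunit of the same ligase, had 198 ± 59.5 normalised reads in CON and 102 ± 10.8 in KO (log2 difference -0.49, SE 0.26, adjusted p = 0.260).

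The largest increases included genes of alternatively activated macrophages and chemokines. Arg1, which encodes arginase, had 29 ± 11.8 normalised reads in CON and 11065 ± 8616 in KO (log2 difference 5.85, SE 0.44, adjusted p = 2.6e-05). Retnla followed at 5.79 (SE 0.45), and the chemokine genes Ccl7 and Ccl24 at 4.88 and 4.39. Car2, which encodes carbonic anhydrase 2, rose from 705 ± 179.6 to 34464 ± 10794 normalised reads (log2 difference 5.27, SE 0.26). The other genes among the 12 largest increases were Cdkn1a (4.89), Wdr72 (4.41), Spp1 (4.28), Gpnmb (4.18), Lgals3 (4.05), Fos (4.0) and Emp1 (3.99). Their adjusted p-values ran from 1.4e-06 for Cdkn1a to 0.00777 for Spp1. Spp1 and Ccl24 varied among the KO libraries, with 5545 ± 7607 and 3494 ± 3414 normalised reads. The 12 largest decreases were Lsm4 (-2.44), Spag5 (-2.37), Dipk2a (-2.36), the dopamine receptor gene Drd4 (-2.33), Peli1 (-2.32), R3hdml (-2.25), the melatonin receptor gene Mtnr1a (-2.16), Gstm1 (-2.07), Crygn (-2.07), Tmprss5 (-2.07), Rnf187 (-2.06) and Lgsn (-2.04). Drd4 went from 655 ± 316 to 27.4 ± 14.1 normalised reads. Of these 24 genes, 23 kept their calls whichever library was left out. Rnf187 lost its call without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.0968). With voom on recovered reads, the calls of Spp1 (adjusted p = 0.512) and Ccl24 (0.333) were lost. With reads divided by the library total, so were these 2 and those of Arg1 (adjusted p = 0.0797), Retnla (0.0559) and Rnf187 (0.188).

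**Figure D2:**
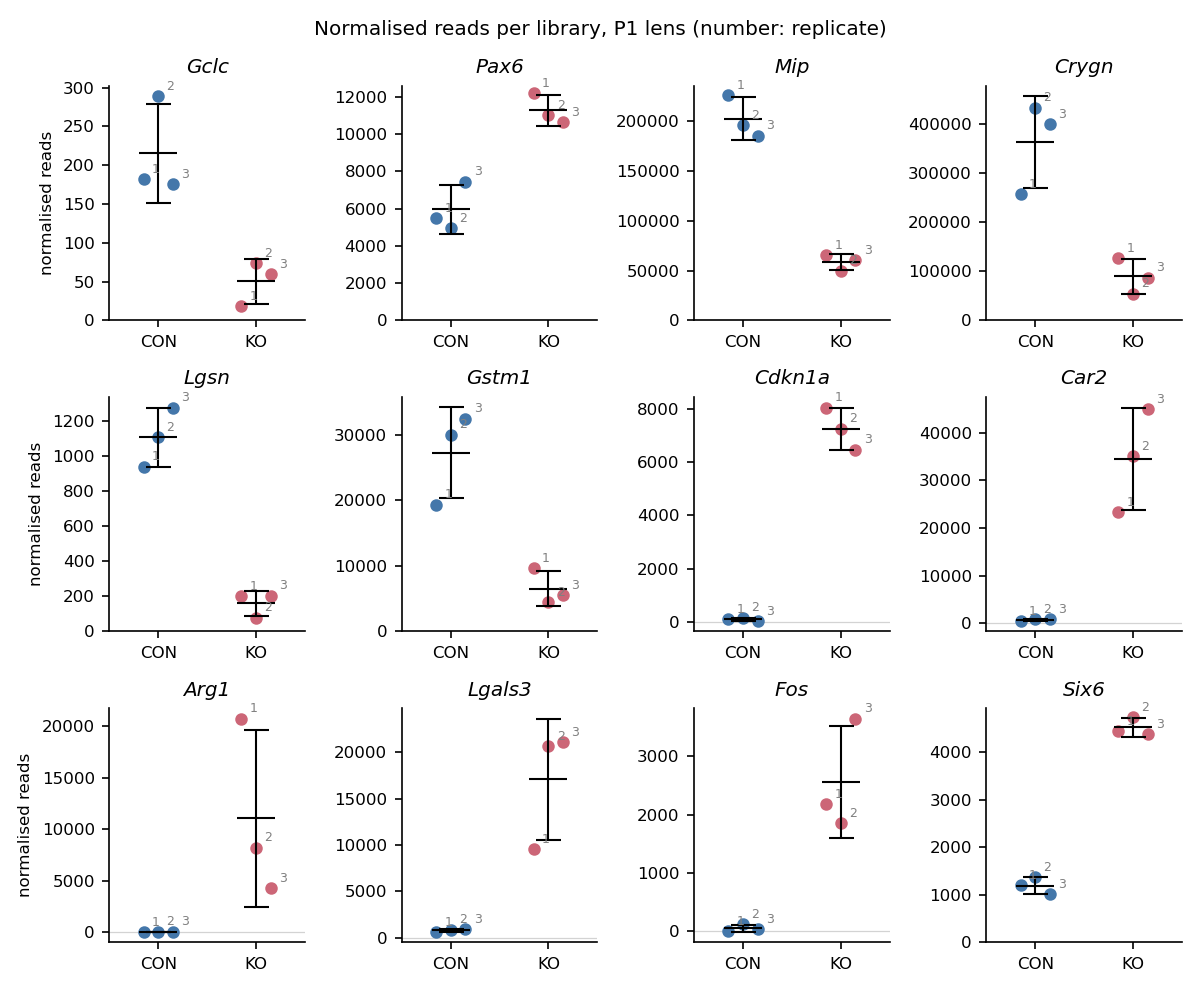
Normalised reads of 12 genes in each library (y axis, linear scale from 0; number beside each point, replicate), with the group mean and SD as black bars. In each panel the 3 KO libraries lie on one side of the 3 CON libraries. For Crygn, Lgsn, Gstm1, Cdkn1a, Car2, Arg1, Lgals3 and Fos the rule for naming genes required this. For any gene, 10% of orderings separate the groups by chance.

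Transcripts of differentiated lens fibre cells were lower in part. Of 29 tested genes of fibre membrane, cytoskeleton and maturation, 16 fell, 1 rose and 12 did not pass (median log2 difference -0.90, camera adjusted p = 5.5e-12; adjusted p = 0.113 with an estimated correlation). Adjusted over the list alone, 22 fell and 1 rose. Mip fell by 1.79 on the log2 scale (SE 0.22), and Lgsn, which encodes the lens glutamine synthetase-like protein lengsin, went from 1108 ± 169 to 161 ± 71.4 normalised reads. The member that rose was Vim, which encodes the intermediate filament protein vimentin (14493 ± 1217 to 24789 ± 2899.9). It lost its call without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.156). The number of fibre genes that fell was 10 without KO 2. Of the 16 crystallins, 10 fell and none rose, with 14 lower and 0 higher adjusted over the list alone (median log2 difference -1.41, camera adjusted p = 1.7e-09; adjusted p = 0.412 with an estimated correlation). Under quantile normalisation, which forces the most abundant genes of every library to equal values, the crystallin median differed from that of all genes by 0.0454 and the list call was lost (adjusted p = 0.744), whereas under the other scalings it stayed lower than that of all genes. With reads divided by the library total, the median was -0.54 for crystallins and -0.23 for fibre genes, where that of all genes was 0.86. Crygn fell by 2.07 (SE 0.33) and Cryba2 from 784914 ± 138343 to 284044 ± 55830.5 normalised reads. Crybb2 stood at 160604 ± 82620.2 in CON and 149591 ± 7892 in KO (adjusted p = 0.944). With voom and reads divided by the library total it was called higher (0.94, adjusted p = 0.0236). The number of crystallins that fell was 15 without CON 1, 3 without CON 2, 3 without CON 3, 5 without KO 1, 4 without KO 2 and 4 without KO 3. The crystallin paralogs are close in sequence, so their reads are not safely separate.

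Lens epithelium genes went both ways. Of 19 tested, 3 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.17, camera adjusted p = 0.292). Pax6, Aqp1 (1.00) and Mab21l1 (0.80) rose. Cdh1, the E-cadherin gene (-1.67), Fgfr3 (-1.27) and Slc38a3 (-1.19) fell. The listed gene Foxe3 had too few reads to be tested. It had 523.5, 83.33 and 3.004 normalised reads in CON 1 to 3 and 3.519, 4.285 and 0 in KO 1 to 3. Its CON 3 value lay within the KO range, so Foxe3 did not separate the groups. The list of PAX6 and its lens regulatory network also split, with 4 of 24 higher and 4 lower, and 8 higher and 7 lower adjusted over the list alone (median -0.21, camera adjusted p = 0.557). Pax6 (0.92, SE 0.21), Mab21l2 (1.46), Meis1 (0.95) and Mab21l1 rose. The transcription factor genes Hsf4 (-1.13) and Maf (-1.17) and the crystallins Crybb1 (-1.50) and Cryaa (-1.36) fell. In the same KO libraries the retinal progenitor gene Six6, not counted in that list, rose from 1198 ± 174 to 4529.8 ± 194 normalised reads. The rise of Pax6 lost its call without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.0714). Calls were also lost for Meis1 without KO 2 or KO 3 (adjusted p up to 0.0920), Mab21l1 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.224) and Maf without KO 2 (adjusted p 0.0527). So were those of Crybb1 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.0985), Cryaa without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.139) and Aqp1 without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.127). Among the falls of epithelium genes, the calls did not hold for Fgfr3 without KO 2 (adjusted p 0.0540) and Slc38a3 without CON 1, CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.104). Of the PAX6 list, the number that rose was 1 without KO 2 or KO 3, and the number that fell 2 without CON 2 or KO 3 and 1 without KO 2. Of the epithelium list, it was 1 without KO 1 and 0 without CON 2, KO 2 or KO 3 for rises and 1 without KO 2 for falls.

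**Figure D3:**
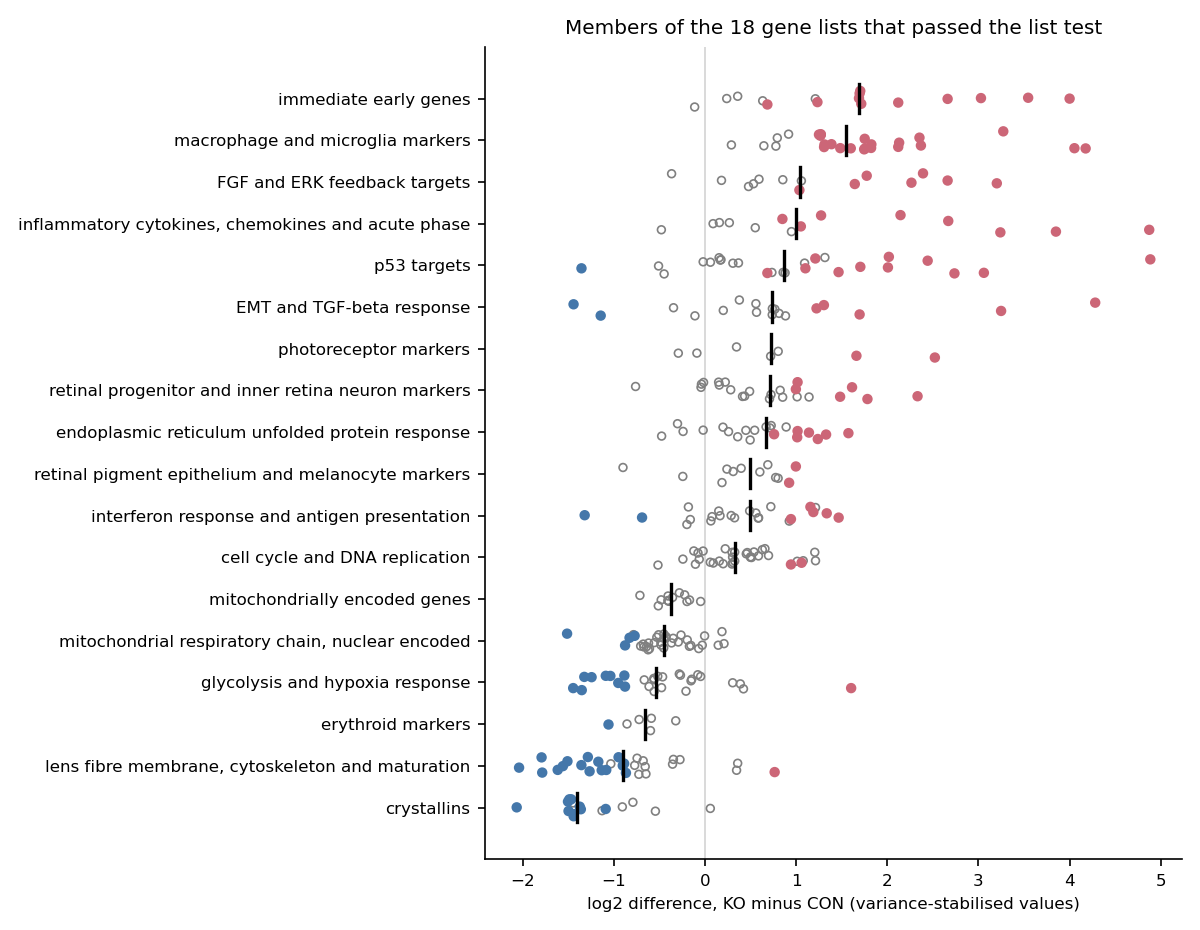
Log2 difference, KO minus CON, of each tested member (x axis) of the 18 gene lists that passed the list test with the preset correlation (y axis). Filled points passed the test over all genes, red higher and blue lower in KO, open points did not pass, and black bars are list medians, which run from -1.41 for crystallins, where quantile normalisation gave a median near that of all genes, to 1.69 for immediate early genes.

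Genes of glutathione metabolism did not move together. Of 24 genes of glutathione synthesis, transport and cycling, 4 rose and 4 fell (4 and 5 adjusted over the list alone), and the list test did not pass (camera adjusted p = 0.633; its median was -0.03 and its mean 0.06). Chac1, which encodes a glutathione-degrading enzyme, rose from 151.7 ± 106 to 1357 ± 342 normalised reads (log2 difference 2.39, SE 0.32). Glrx (1.30), Gpx3 (1.36) and Gpx7 (0.86) rose. Gclc, Ggct (-1.28), Gpx1 (-1.02) and Slc3a2 (-0.72) fell. Among 18 glutathione S-transferases, 6 fell and 2 rose (6 and 5 adjusted over the list alone; camera adjusted p = 0.295). The 6 that fell were all of the Gstm class, whose members share sequence, so their reads are not safely separate. Gstm1 went from 27282 ± 6964 to 6534 ± 2728 and Gstm7 from 2617 ± 453 to 928 ± 165 normalised reads. Gsta4 (1.11) and Gstt1 (1.09) rose. Of 26 targets of the oxidative stress regulator NRF2, 5 rose and 4 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.648). Sqstm1 (2.03, SE 0.25), Ephx1 (1.93), Nqo1 (1.11), Gsta4 and Ugdh (0.92) rose, and Gstm1, Akr1b8 (-1.0), Hmox1 (-1.31) and Tkt (-0.67) fell. With 1 library left out, calls were lost for Gpx7 without CON 1, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.167), Gpx1 without CON 2 or KO 2 (adjusted p up to 0.0850) and Slc3a2 without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.206). Gsta4 lost its call without CON 2, KO 1 or KO 2 (adjusted p up to 0.0762) and Gstt1 without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.0898). Of the NRF2 targets, Nqo1 lost its call without CON 2, KO 2 or KO 3 (adjusted p up to 0.103), Ugdh without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.131), Akr1b8 without KO 2 or KO 3 (adjusted p up to 0.0904), Hmox1 without CON 1, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.147) and Tkt without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.172). The number of transferases that fell was 3 without CON 2, CON 3, KO 2 or KO 3. For the glutathione list that number was 2 without KO 1 or KO 3 and 1 without CON 2 or KO 2. For the NRF2 list the number that rose was 3 without KO 1 or KO 3 and 2 without CON 2 or KO 2, and the number that fell 2 without CON 3 or KO 1 and 1 without KO 2 or KO 3.

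Stress response genes rose in part. Of 26 p53 targets, 11 rose and 1 fell (14 and 1 adjusted over the list alone; median log2 difference 0.87, camera adjusted p = 2.0e-06; adjusted p = 0.113 with an estimated correlation). Cdkn1a rose by 4.89 (SE 0.25) and Plk2 by 2.74 (SE 0.30), and Sesn1 fell by 1.36 (SE 0.22). The number of targets that rose was 7 without CON 2, KO 2 or KO 3. Of 21 genes of the endoplasmic reticulum unfolded protein response, 7 rose and none fell (11 and 0 adjusted over the list alone; median log2 difference 0.67, camera adjusted p = 0.000133; adjusted p = 0.113 with an estimated correlation). The chaperone gene Hspa5 went from 18269 ± 4663 to 53881 ± 6052 normalised reads and Creld2 rose by 1.33. The number that rose was 4 without KO 2 or KO 3. Of 31 genes of the ATF4 and integrated stress response, 6 rose and 3 fell (7 and 5 adjusted over the list alone), and the list test did not pass (camera adjusted p = 0.295). Atf3 rose by 3.03 (SE 0.30) and Gdf15 from 7.23 ± 6.37 to 744 ± 299 normalised reads (adjusted p = 0.0845 with voom on recovered reads). The serine synthesis gene Phgdh (-1.30) and the amino acid transporter genes Slc7a5 (-0.95) and Slc3a2 (-0.72) fell. The calls were lost for Phgdh without CON 2 or KO 2 (adjusted p up to 0.0583), Slc7a5 without KO 2 (adjusted p 0.124) and Slc3a2 without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.206), so that the number that fell was 1 without CON 2 and 0 without KO 2. Of 19 heat shock genes, Hspa4l rose (1.62, SE 0.24), none fell and the list test did not pass (camera adjusted p = 0.392); 1 rose and 0 fell adjusted over the list alone, and the number that fell was 2 without CON 1.

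Immediate early genes, which respond within minutes to growth factors, stress or tissue handling, rose in part. Of 16 tested, 11 rose and none fell (13 and 0 adjusted over the list alone; median log2 difference 1.69, camera adjusted p = 7.6e-10; adjusted p = 0.113 with an estimated correlation). Fos went from 53.6 ± 62.2 to 2558 ± 957 normalised reads, and Atf3 (3.03) belonged to the same list. Of 14 feedback targets of FGF and ERK signalling, 7 rose and none fell (9 and 0 adjusted over the list alone; median log2 difference 1.05, camera adjusted p = 1.2e-06; adjusted p = 0.128 with an estimated correlation). The ERK phosphatase gene Dusp6 went from 543 ± 293 to 6045 ± 1119 and Egr1, which both lists hold, from 33.1 ± 36.1 to 817 ± 109 normalised reads. Macrophage markers, whose cells also express several of these genes, had a median log2 difference of 1.54 in the same libraries.

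Markers of macrophages and microglia rose in part. Of 26 tested, 21 rose and none fell (24 and 0 adjusted over the list alone; median log2 difference 1.54, camera adjusted p = 4.3e-14; adjusted p = 0.189 with an estimated correlation). Lgals3 went from 812 ± 148 to 17093 ± 6524 and Gpnmb from 582 ± 142 to 15727 ± 8999.6 normalised reads. Both are also expressed outside macrophages. The 5 that did not pass were Cx3cr1, Laptm5, Aif1, H2-Ab1 and C1qc, with differences from 0.29 to 0.92. The number that rose was 12 without KO 2 and 9 without CON 2 or KO 1. Of 14 inflammatory cytokine, chemokine and acute phase genes, 8 rose and none fell (9 and 0 adjusted over the list alone; median log2 difference 1.00, camera adjusted p = 7.0e-07; adjusted p = 0.113 with an estimated correlation). Ccl7 went from 87.9 ± 24.4 to 6916 ± 2082 normalised reads. Ptgs2, which encodes cyclooxygenase 2, had no reads in any CON library and 704 ± 109 in KO, at least 447-fold higher against a floor of 3 reads over the CON libraries together, or 224-fold if both mates of read pairs were counted. The number of inflammatory genes that rose was 5 without KO 1, KO 2 or KO 3. Of 23 interferon response and antigen presentation genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone; median log2 difference 0.49, camera adjusted p = 0.0375; adjusted p = 0.698 with an estimated correlation). H2-K1 (1.47), Tapbp (1.16), Ddx58 (1.33), H2-D1 (1.19) and Ifi35 (0.94) rose, and Rsad2 (-1.32) was among those that fell; H2-K1 and H2-D1 are similar in sequence. The list call was lost without CON 1 (adjusted p = 0.160), CON 3 (0.214), KO 1 (0.173) or KO 2 (0.0758). Calls were lost for Tapbp without KO 2 (adjusted p 0.0802), Ddx58 without CON 2, CON 3, KO 1 or KO 2 (adjusted p up to 0.112) and H2-D1 without CON 2, CON 3, KO 1 or KO 2 (adjusted p up to 0.109). The same held for Ifi35 without any 1 of the 6 libraries (adjusted p up to 0.162) and Rsad2 without CON 1, CON 2, KO 2 or KO 3 (adjusted p up to 0.156). The number of interferon genes that rose was 2 without CON 2, CON 3 or KO 1 and 1 without KO 2, and the number that fell 1 without CON 3 or KO 1 and 0 without CON 1, CON 2, KO 2 or KO 3.

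Markers of vessels and blood were compared next. None of 15 endothelial markers passed the test (median -0.11, camera adjusted p = 0.264), nor did any of 7 pericyte and smooth muscle markers (median 0.32, camera adjusted p = 0.317; 0.985 above all genes with voom on recovered reads), and none of either list passed adjusted over the list alone. The number of endothelial markers that rose was 1 without CON 1, and the number that fell 2 without CON 3 and 1 without CON 1 or KO 1. Of 6 erythroid markers, 1 fell and none rose (4 and 0 adjusted over the list alone; median log2 difference -0.66, camera adjusted p = 0.00261; adjusted p = 0.302 with an estimated correlation). It was Hba-a2, an alpha globin gene that shares sequence with Hba-a1 (3008 ± 846 to 1362 ± 488 normalised reads), and it lost its call without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.154), whereas 4 markers fell without CON 1. Only 3 neutrophil, mast cell and lymphocyte markers had enough reads to be tested, and none passed.

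Glycolysis genes were lower in part. Of 28 glycolysis and hypoxia response genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone; median log2 difference -0.54, camera adjusted p = 6.5e-06; adjusted p = 0.189 with an estimated correlation). With reads divided by the library total the list median was 0.29, below the 0.86 of all genes, and the list test still pointed downward (camera adjusted p = 0.000109). Aldoc went from 12670.4 ± 2529.8 to 5188 ± 564 and P4ha1 from 11022 ± 1039 to 4056 ± 1348 normalised reads, and Pfkp rose by 1.6 (SE 0.30). The number that fell was 5 without KO 3 and 4 without KO 2. The glycolysis list was not compared with random lists matched on transcript length and expression. Whether its fall exceeds that of genes of like length and expression was thus not tested. Of 35 nuclear genes of the mitochondrial respiratory chain, 4 fell and none rose (4 and 0 adjusted over the list alone; median log2 difference -0.45, camera adjusted p = 1.7e-06; adjusted p = 0.516 with an estimated correlation). With reads divided by the library total the list test pointed upward and did not pass (adjusted p = 0.498), although the list median lay 0.48 below that of all genes. The list median lay at percentile 22.8 of random lists matched on transcript length and expression. The members that fell were Ndufa1 (-1.52), Cox6a1 (-0.83), Cox5b (-0.88) and Cox8a (-0.77). The number that fell was 20 without CON 1, 2 without KO 1 and 1 without CON 2, CON 3, KO 2 or KO 3. The calls were lost for Cox6a1 without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.151), Cox5b without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.177) and Cox8a without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.182). None of the 12 mitochondrially encoded genes passed, also adjusted over the list alone, although the list test did (median log2 difference -0.38, camera adjusted p = 0.0176; adjusted p = 0.649 with an estimated correlation). It was lost without CON 2 (adjusted p = 0.0945) or KO 1 (0.173), and the number of these genes that fell was 1 without CON 1. With reads divided by the library total their median was 0.42 and the list did not pass, and the 13 genes of the list, the untested 1 included, took 0.216% ± 0.0280 of reads in CON and 0.302% ± 0.0970 in KO (SD, n = 3). Of 31 cholesterol and fatty acid synthesis genes, 3 rose and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.579). They were Msmo1 (0.86), Scd1 (1.26) and Sqle (0.77), and they lost their calls, Msmo1 without KO 1, KO 2 or KO 3 (adjusted p up to 0.0919), Scd1 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.153) and Sqle without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.200). The number of synthesis genes that fell was 2 without CON 1.

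Of 18 genes of epithelial-mesenchymal transition and the TGF-beta response, 5 rose and 2 fell (10 and 2 adjusted over the list alone; median log2 difference 0.74, camera adjusted p = 0.00405; adjusted p = 0.128 with an estimated correlation). Tgfbi went from 44.5 ± 45.9 to 1380 ± 457 normalised reads (adjusted p = 0.0624 with voom on recovered reads), and Spp1, Ccn1 (1.70), Mmp2 (1.30) and Fn1 (1.22) rose; macrophages also express Spp1 and Tgfbi. Thbs1 (-1.44) and Tpm2 (-1.15) fell. Calls were lost for Mmp2 without KO 2 (adjusted p 0.0808), Fn1 without CON 1, CON 2, CON 3, KO 1 or KO 2 (adjusted p up to 0.164) and Tpm2 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.124), and the number that rose was 3 without KO 2. Of 23 WNT and BMP targets, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.709; median -0.05, mean 0.03). Id3 (1.35, SE 0.23), Lgr5 (1.62) and Bambi (1.38) rose. The secreted WNT inhibitor gene Sfrp1 (25745 ± 2509 to 8132 ± 1193 normalised reads), Id2 (-1.21) and Msx2 (-0.97) fell. Calls were lost for Lgr5 without KO 1 (adjusted p 0.0562), Bambi without CON 3 or KO 2 (adjusted p up to 0.116) and Msx2 without CON 2, KO 1, KO 2 or KO 3 (adjusted p up to 0.110). The number of WNT and BMP targets that fell was 5 without CON 3. Of 34 cell cycle and DNA replication genes, 2 rose, the replication genes Mcm3 (0.94) and Mcm4 (1.06), and none fell. Neither passed adjusted over the list alone (median log2 difference 0.32, camera adjusted p = 0.0147; adjusted p = 0.698 with an estimated correlation). The list call was lost without CON 3 (adjusted p = 0.227) or KO 1 (0.471), and the calls of Mcm3 without CON 2, CON 3, KO 1 or KO 2 (adjusted p up to 0.212) and of Mcm4 without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.190).

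Markers of other eye cells were also compared. Of 23 markers of retinal progenitors and inner retina neurons, 6 rose and none fell (8 and 0 adjusted over the list alone; median log2 difference 0.71, camera adjusted p = 0.000400; adjusted p = 0.516 with an estimated correlation). Six6 (1.78, SE 0.20) had the smallest p-value. Without CON 3 the list call was lost (adjusted p = 0.0549), and the number that rose was 3 without KO 2 or KO 3. Of 7 photoreceptor markers, the cone genes Arr3 (2.0 ± 3.47 to 413 ± 94.2 normalised reads) and Opn1sw (1.66) rose and none fell (2 and 0 adjusted over the list alone; median log2 difference 0.72, camera adjusted p = 0.0353; adjusted p = 0.412 with an estimated correlation). The list call was lost without CON 1 (adjusted p = 0.117), CON 3 (0.0814) or KO 3 (0.0768), and the call of Opn1sw without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.113). With voom on recovered reads, the list (adjusted p = 0.147) and Opn1sw (0.397) lost their calls. Of 12 pigment epithelium and melanocyte markers, Rlbp1 (1.00) and Tyrp1 (0.92) rose and none fell (6 and 1 adjusted over the list alone; median log2 difference 0.50, camera adjusted p = 0.0314; adjusted p = 0.412 with an estimated correlation). That list call was lost without CON 2 (adjusted p = 0.0786), KO 1 (0.0979) or KO 2 (0.0511), and the calls of Rlbp1 without KO 1, KO 2 or KO 3 (adjusted p up to 0.101) and of Tyrp1 without CON 2, KO 1 or KO 2 (adjusted p up to 0.172). The number of pigment cell markers that fell was 1 without KO 1. Of 7 glia and Schwann cell markers, Slc1a3 (2.03, SE 0.22) and Apoe (1.40, SE 0.20) rose and none fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.118). Of 6 corneal and surface epithelium markers, Jup (1.29) rose and Cdh1 (-1.67) fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.579), and Jup lost its call without KO 2 (adjusted p 0.0565), whereas 2 rose without KO 3. Of the 25 members of that list, the others had too few reads to be tested. Among them Dsp had no reads in CON and 66.9, 98.6 and 111 in KO 1 to 3, and Cldn4 (458) and Krt14 (76.2) had reads in KO 1 only, where Krt17 also stood out (300.3, against 3.67 in KO 2 and 0 elsewhere). Of 15 mesenchyme and keratocyte markers, Fbn1 (1.44), Col6a1 (1.38), Fbln1 (1.28) and Postn (1.78) rose and Col6a3 (-1.76), Pdgfra (-1.40) and Ogn (-1.31) fell (6 and 4 adjusted over the list alone; camera adjusted p = 0.952; median -0.08, mean 0.16). Calls were lost for Col6a1 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.121), Fbln1 without CON 2, CON 3, KO 2 or KO 3 (adjusted p up to 0.124) and Postn without CON 2, KO 1 or KO 2 (adjusted p up to 0.0977). Of 3 skeletal muscle markers tested, Casq2 rose (1.53, adjusted p = 0.00815) and lost its call without KO 2 (adjusted p 0.0516); 1 rose and 1 fell adjusted over the list alone. With voom on recovered reads, calls were also lost for Gstt1 (adjusted p = 0.0567), Ugdh (0.0691), H2-D1 (0.0626), Ddx58 (0.177), Scd1 (0.280), Mmp2 (0.0567), Fn1 (0.116), Lgr5 (0.138), Mcm3 (0.0666), Mcm4 (0.0664), Mab21l1 (0.0592), Tyrp1 (0.0598), Col6a1 (0.146), Postn (0.185) and Casq2 (0.0592).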

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

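The settings that scaled by total or non-crystallin reads, left out the crystallins or removed the length trend were chosen after the results were seen, and the cause of the changes below was not tested unless said. Against 793 genes higher and 504 lower, 340 were higher and 462 lower with the stricter filter, and 421 higher and 472 lower with voom on recovered reads. With library weights, which gave KO 2 and KO 3 weights of 2.88 and 2.63, 1219 were higher and 933 lower. With the replicate block, which takes degrees of freedom and pairs numbers that showed no pairing, 309 were lower and Gclc stood at -1.01 (adjusted p = 0.0643). With the covariate for library name style, by construction a comparison of KO 1 alone with CON, 204 were higher and 39 lower and Gclc stood at -1.38 (adjusted p = 0.110). A threshold of 1 log2 unit left 335 lower. Scaling by total reads gave 3314 higher and 85 lower, 6 lists higher, and Gclc at -1.45 (adjusted p = 0.124); Tkt (0.13), Cox8a (0.078), Slc3a2 (0.12) and Cox6a1 (0.024) were among 44 called genes that changed sign, and 41 of 127 named genes lost their call, with a median of 0.86 over all genes. Scaling by non-crystallin reads gave 292 lower and Gclc at -2.00 (adjusted p = 0.0920). Gclc also missed the threshold without the filter on low values (-1.01, adjusted p = 0.0752), with voom (-2.16, 0.0609) and with log2 of normalised reads plus 1 (-2.25, 0.0709).

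With 1 library left out, the genes higher ranged from 357 to 1085, the genes lower from 1.8e+02 (rounded to 2 digits) to 858, and the Gclc difference from -1.13 to -0.83; lists higher ranged from 8 to 11 and lists lower from 5 to 6. Of 127 named genes with a call, 69 kept it in all 6 such fits and 58 lost it in at least 1. Crybb2, not called in the reported fit, was 0.06 there, -0.067 with equal library medians and -0.14 with library weights, and ranged from -0.44 to 0.42 with 1 library left out. With voom and total reads as library size it was called higher (0.94, adjusted p = 0.0236), where the median over all genes was 0.86. Camera with an estimated correlation called 0 lists higher and 0 lower, against 12 and 6 with the preset correlation; fry, which tests the members of each list alone, called 10 and 4.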

Other observations

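All tests below were chosen after the results were seen, apart from the neighbours of Gclc and the counts over other splits. The prediction for the ciliary margin genes was written before that test was run, but after the rises of Pax6 and Six6 were seen. Aqp4, among the ciliary margin genes, was already in the fixed glia list. 3 groups of genes outside the fixed lists, picked after the results were seen, differed in part. None of 30 cytoplasmic ribosomal protein genes rose and 15 fell (27 adjusted over the list alone; median log2 difference -0.71), among them Rps2 (-1.89, SE 0.33) and Rplp2 (9849.6 ± 1597 normalised reads in CON and 4487 ± 303 in KO). Many ribosomal protein genes have processed pseudogenes of similar sequence. Genes of short transcripts were lower in general, with a median of -0.26 in the 10% of genes with the shortest transcripts against 0.17 in the 10% with the longest, and the ribosomal median lay at percentile 0.110 of 10000 random lists matched on length and expression, whose own median was -0.47. The median of the respiratory chain genes (-0.45) lay at percentile 22.8 of such lists, whose median was -0.39. Its fall was thus not set apart from that of other genes of like length and expression. Of 27 lysosome genes 7 rose and none fell (10 and 0 adjusted over the list alone), with Ctsd at 22826 ± 2531 in CON and 48059.6 ± 8367 in KO and Grn at 0.99 (SE 0.21). Macrophages, whose markers had a median of 1.54 in the same libraries, also express these genes. Ctsd lost its call without KO 2 or KO 3 (adjusted p up to 0.0568) and Grn without KO 2 or KO 3 (adjusted p up to 0.0876).

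Genes of the basement membrane, from which the lens capsule is built, were lower in part. Of 17 genes, Col4a2 (4835 ± 1092 in CON and 1461 ± 311 in KO, log2 difference -1.61), Col4a1 (-1.51, SE 0.24) and Nid1 (-0.81, SE 0.22) fell and Col18a1 (1.15, SE 0.29) rose (5 lower and 1 higher adjusted over the list alone). Nid1 lost its call without CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.185) and Col18a1 without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.101). Genes without a read in any CON library included the cornified envelope gene Cdsn (at least 127-fold with a floor of 6 reads, 400.4 ± 180.1 in KO). The sex-linked genes differed between libraries without following the groups: Ddx3y had 593, 208 and 1712 normalised reads in CON 1 to 3 and 0, 1818 and 2158 in KO 1 to 3, and Xist 25.8, 234 and 0 in CON and 68.6, 91.2 and 244 in KO.

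Of 26 macrophage markers, 21 were higher in KO. Vessels carried over with their endothelium are argued against, in these libraries, by the endothelial markers, whose median was -0.108 (95% bootstrap interval -0.393 to 0.0159) where 0.771, 0.5 of the macrophage median, was the bound. The bootstrap resampled the genes of the list as if independent. Its interval thus leaves out the spread between libraries. Pericyte markers, 0.985 above all genes with voom, leave cells around vessels open. More macrophages of unchanged profile stay open: 5 markers still differed after centring on the list mean (C1qc lower; Cd74, Gpnmb, Lgals3 and Adgre1 higher), as many as the highest of 100 simulated draws of a uniform shift (5), and 2 with Lgals3 and Gpnmb left out. Also open as untested hypotheses are a response of macrophages to KO lenses, a change in their state, and Lgals3 and Gpnmb made by lens or pigment cells, which KO 1 may point to, since it had the most Adgre1 (1803 normalised reads, against 474 and 335 in KO 2 and 3) but the least Lgals3 (9564, against 20655 and 21061).

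Of 16 crystallins, 10 were lower in KO, and quantile normalisation lost the list call (adjusted p = 0.744). Scaling as the only source is argued against by the raw shares of reads, as the highest KO share lay 12 points below the lowest CON share (difference -12). The size of the fall did depend on scaling. With reads divided by the library total the crystallin median was -0.54, against -1.41 as deposited, and the median over all genes was 0.86. Uniform dilution of fibre cell RNA by RNA of other cells stays open: 5 crystallins still differed after centring on the list mean (Cryab, Crybb2 and Crygs higher, Crygn and Cryga lower; highest 2 in 100 simulated draws), but 0 with Cryab, Crybb2 and Crygs left out, which other cells also express. These 3 were chosen after the values were seen. Loss of short or abundant transcripts stays open too: the crystallin median of -1.41 lay at percentile 0 of random lists matched on length and expression, but these had a median of -0.55 and the crystallins lay 6.66 log2 units above the matched genes in expression. A delay or loss of fibre differentiation remains an untested hypothesis.

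Pax6 and Six6 were higher in KO. Neural retina carried over with its neurons stays open: of 12 retinal neuron genes 1 rose (Syt1, 1.48), and their median of 0.346 had a 95% bootstrap interval (0.152 to 0.779) that held 0.459, 0.5 of the Pax6 difference, but lay below 0.891, 0.5 of the Six6 difference. This interval too came from resampled genes and leaves out the spread between libraries. The deposited scale shrinks differences of genes with few reads. The 12 genes held no photoreceptor genes. Of 7 photoreceptor markers tested, Arr3 (2.52, adjusted p = 0.000263) and Opn1sw (1.66) rose and 5 did not pass. The others of the 25 listed had too few reads to be tested. Among them Sag had 3.22, 0 and 0 normalised reads in CON 1 to 3 and 17.6, 55.1 and 67.8 in KO 1 to 3. Nr2e3 had none in CON and 1.17, 36.7 and 52.7 in KO. Other untested markers went the other way, as Gnat1 had reads in CON 2 only (48.1) and Nrl was highest in CON 2 (76.9). Opn1sw lost its call with voom on recovered reads. Ciliary epithelium carried over with the KO lenses may contribute: all 8 ciliary margin genes tested were higher, at percentile 98.9 of random lists matched on expression, and Wfdc1 (1.61, SE 0.21) and Zic2 (0.92, SE 0.27) passed (2 adjusted over the list alone). By the same measure the 12 retinal neuron genes, 10 of them higher, lay at percentile 91.4. With reads divided by the library total, the neuron median lay 0.805 above that of all genes and the ciliary margin median 0.615. These values do not tell the 2 tissues apart. Zic2 lost its call without CON 2, CON 3, KO 1, KO 2 or KO 3 (adjusted p up to 0.227) and Syt1 without CON 3, KO 2 or KO 3 (adjusted p up to 0.1), and both with voom on recovered reads (0.219 and 0.108). Carried-over tissue and a change of gene regulation within lens cells could both apply, and the latter was not tested.

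Strain variants carried with the altered Gclc allele were tested as a hypothesis: of the 50 tested genes on each side of Gclc on chromosome 9 (GRCm38 order), 16 of 100 were called, 16% against 11.26% of others (one-sided Fisher exact p = 0.0955), which leaves it open. Of the genes named above, Wdr72 (4.41, 13 genes from Gclc) and Gsta4 (1.11, 6 genes away) were among the 16. For them the design cannot tell an effect of Gclc from a linked variant. There are 10 splits of the libraries into 3 and 3, too few for a share under 0.05. The real split called 1297 genes, against 0 at most in the others (1 of 10 splits as large), and 18 lists, against 14 at most (1 of 10).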
